A study of Mus musculus with 2 samples.

How the data were processed

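Single-cell RNA sequencing (10x Genomics, UMI counts per gene and cell) was available for endothelial cells of the adrenal glands of female mice aged 12 weeks. There was 1 wild-type (WT) library and 1 library from mice labelled VEGF/LysM. Per the labels, the glands were minced and digested with a cold-active protease, and viable CD31+ CD45- cells were sorted before loading. The number of mice behind each library is not given in the sources used here.

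The deposited values were raw UMI counts per gene and cell, with no normalization, and whole numbers in both libraries. The authors' processing notes named Cell Ranger 7.0.1 and Seurat with the mm10 genome, and the matrix header named Cell Ranger 7.0.0. The annotation release, the cell-calling settings and whether intronic reads were counted are not given in the sources used here. The files listed only barcodes already called as cells, so the RNA of empty droplets could not be measured. Of 54838 gene identifiers in the files, 54809 matched GENCODE M21, from which coordinates (GRCm38/mm10) and gene-body lengths were taken.

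The WT library held 6276 barcodes with 8606348 UMIs (median 1174.5 per barcode, range 454 to 14817). The VEGF/LysM library held 3807 barcodes with 10323972 UMIs (median 2336, range 500 to 25424). Barcodes with at least 500 UMIs, at least 300 genes and at most 15% mitochondrial UMIs were kept, which left out 142 WT and 14 VEGF/LysM barcodes. Scrublet scores (scanpy 1.11.5) were computed per library. Their automatic threshold called 0 WT and 3 VEGF/LysM barcodes and was not used. Instead the highest-scoring barcodes were left out at 0.8% per 1000 barcodes, which removed 315 WT (5.02%) and 116 VEGF/LysM barcodes (3.05%). Retained were 5820 WT and 3677 VEGF/LysM cells.

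Both libraries were clustered together without integration: log-normalization to 10000, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering (igraph 0.11.9) at resolution 1, giving 17 clusters. Clusters were named from 18 marker lists. Names rested on the mean enrichment of a marker list in a cluster over the other cells, except that capillary-like rested on Cd36 and Car4, with Gpihbp1 also enriched. An endothelial cluster with no such name was called Plvap-high when its pooled Plvap level reached 700 CPM, and other endothelial below that. The limits by which clusters were named, and the name Plvap-high, were set after the clusters had been seen. Because genes that differ between the libraries can move cells between clusters, the shares of endothelial classes came from a clustering that left out 457 genes, reached after 7 rounds: those whose ratio lay beyond 1.25-fold by its interval in all endothelial cells, and leading genes of clusters that did so within their cluster. A second scheme that left out leading genes only was also run, for 8 rounds, and the shares of every round of both had been seen when one was chosen. The capillary-like, arterial-like and pooled Plvap-high or tip-like differences had the same directions in all rounds of both schemes. Tip-like cells were pooled with Plvap-high cells for shares after their own share had proved unstable over rounds.

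For gene ratios, UMIs were summed over the cells of each library and scaled to CPM over the summed total. Ratios are VEGF/LysM over WT, with exact conditional binomial 95% intervals. CPM values carry exact Poisson intervals, and shares of cells exact binomial (Clopper-Pearson) intervals. All intervals cover counting error only. Where a count was 0, the upper limit was taken as 3 counts. A gene was measured in a group of cells when it had at least 50 UMIs over both libraries. A class was compared when it had at least 100 cells in each library. With 1 library per group no p-value or standard error is given, there was no replicate check, and counts of genes that differ describe these 2 libraries only.

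For 26 gene lists the median log2 ratio of measured members was set against 10000 random lists of equal size matched on mean expression in 20 bins. Its percentile among these describes the 2 libraries and is not a p-value. The 95% range of a median came from 1000 Poisson redraws of the counts. Members at least 1.25-fold higher or lower were counted. List medians are given for all endothelial cells and for Plvap-high cells only, and list members for all endothelial cells only. Both limits were set after a first run had shown that small classes reversed under alternatives. The VEGF-A-responsive, oxidative phosphorylation and lipid lists are given in every class, and were added there after their values were seen. So were the capillary and arterial marker medians in arterial-like cells. For measures per cell, each cell was thinned at random to 1000 UMIs and shallower cells were left out. For the contrast between classes, cells were reclustered without any listed gene, and each class was compared with the other endothelial cells of the same library.

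Named genes followed a rule. In all endothelial cells and in the largest class, the 12 genes per direction whose 95% bound lay farthest from 1 were named, and 6 per direction in each other class. They needed 50 UMIs over both libraries and 20 CPM in at least 1. Mitochondrial, ribosomal-protein and haemoglobin genes, unnamed gene models, markers of non-endothelial cells, and genes over 5-fold higher in non-endothelial cells were left out. Vegfa, Lyz2, Kdr, Flt1 and Flt4 were always named, and so were up to 4 members per list with the largest log2 ratio and 20 CPM. Genes named outside this rule are marked as chosen after their values were seen. The gene lists, marker lists, filters, naming rule and 16 alternatives were fixed before the data were examined. A further 4 lists (adipocyte, myeloid, B cell and nuclear-retained genes) were written for tests of explanations.

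The alternatives were looser (200 genes, 25% mitochondrial, no UMI minimum) and stricter cell filters (1500 UMIs, 800 genes, 10%), no doublet removal, resolutions 0.5 and 2, clustering on cells thinned to 1000 UMIs, Seurat 5.3.0 CCA integration (R 4.3.3), and clustering without listed and marker genes. For ratios they were median-of-ratios scaling, TMM scaling (edgeR 4.0.16), CPM without mitochondrial and ribosomal-protein genes, the mean of per-cell CPM, cells thinned to 1000 UMIs, minimums of 20 or 200 UMIs, and an equal mix of classes. A further 7 alternatives were chosen after seeing the data: clustering with all variable genes for the shares, VEGF/LysM cells thinned to the WT median depth, leaving out cells with Stab2-type markers, an equal mix of clusters, leaving out a cluster led by B-cell genes (for the shares) or one led by proliferating markers (for the ratios), and CPM without genes that overlap rRNA repeats.

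The ratio and list steps were tested on simulated data, drawn as independent Poisson counts at each library's depth from the pooled expression of both with known folds. The intervals assume such counts, so this checks the calculation only. The draws held no variation between libraries or cells and no shared regulation within lists. In all endothelial cells (12259 genes), intervals held the true fold for 95.4% of unchanged genes, 95.7% at 1.25-fold, 96.0% at 1.5-fold, 94.0% at 2-fold and 89.6% at 4-fold. Of 100 unchanged lists of 15 genes, 8.0% lay outside the central 95% of matched lists. Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were also used.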

Results

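Endothelial cells of the mouse adrenal gland, sorted as CD31+ CD45- cells, were profiled by single-cell RNA sequencing in 2 libraries, 1 labelled WT and 1 labelled VEGF/LysM. After filtering, the WT library held 5820 cells with a median of 1163 UMIs and 860 genes per cell. The VEGF/LysM library held 3677 cells with a median of 2317 UMIs and 1446 genes. Endothelial clusters made up 5680 WT cells with 7404348 UMIs and 3523 VEGF/LysM cells with 8884685 UMIs. Every comparison below is between 2 libraries and not between conditions.

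The comparison asked how VEGF-A made by macrophages bears on the diversity of endothelial cells in the gland. LysM names the gene Lyz2, which macrophages express, and VEGF-A is encoded by Vegfa (ENSMUSG00000023951, chromosome 17, 46016993 to 46032369, minus strand, GRCm38/mm10). Endothelial cells held little Vegfa, 5.94 CPM (44 UMIs, 95% interval 4.32 to 7.98) in WT and 5.18 CPM (46 UMIs, 3.79 to 6.91) in VEGF/LysM. The adrenocortical-like cells that passed the gate held more, 210.2 CPM (128 to 325) in 36 WT cells and 157 CPM (114 to 211) in 44 VEGF/LysM cells. The myeloid-like cells that passed the gate had 0 Vegfa UMIs in 89 WT and 88 VEGF/LysM cells, which allows up to 11.3 and 6.35 CPM. These cells also held endothelial RNA (Kdr at 1429 and 1274 CPM, Flt1 at 1632 and 1984 CPM), so the limits are for mixed RNA and are looser for myeloid RNA alone. The CD45- gate removes most macrophages, and the labels do not state the allele, so Vegfa in these cells does not check the genotype.

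The receptors of VEGF-A were abundant in endothelial cells of both libraries. Kdr stood at 2440.5 CPM (2405 to 2476) in WT and 2184 CPM (2154 to 2215) in VEGF/LysM, a log2 ratio of -0.16. Flt1 was nearly equal, at 3301 and 3336 CPM. Flt4, the receptor of VEGF-C and VEGF-D, was lower in the VEGF/LysM library (367 and 279 CPM, log2 -0.39, -0.47 to -0.31). Within Plvap-high cells the log2 ratios were -0.07 for Kdr (0.01 under the stricter cell filter), 0.13 for Flt1 and -0.19 for Flt4. In capillary-like cells they were -0.18 for Kdr, -0.21 for Flt1 and -0.97 (-1.36 to -0.58) for Flt4 (122 and 62.3 CPM). Flt4 was more abundant in Plvap-high cells (423 and 372 CPM), and WT capillary-like cells also held more Plvap (170 and 92.6 CPM). How much RNA of Plvap-high cells adds to the Flt4 ratio was not tested. In arterial-like cells the log2 ratios were -0.60 for Kdr, 0.06 for Flt1 and -0.84 for Flt4. Without the 14 WT cells and 1 VEGF/LysM cell that carry Stab2 and related transcripts, they were -0.33 for Kdr and -0.15 (-0.74 to 0.46) for Flt4. In tip-like cells Kdr was at -0.05 and Flt4 at -0.36. Flt1 in tip-like cells had a log2 ratio of 0.11, which turned negative under 4 alternatives, down to -0.18 without doublet removal. Lyz2 in endothelial cells was low, 7.70 CPM (5.83 to 9.97) in WT and 13.3 CPM (10.99 to 15.9) in VEGF/LysM, and its log2 ratio of 0.79 became -1.09 under the stricter cell filter. Arterial-like cells held 26 of the 57 WT and 85 of the 118 VEGF/LysM Lyz2 UMIs (82.3 and 136 CPM), while Plvap-high cells had 4.05 and 3.28 CPM (0.81-fold, 0.40 to 1.61).

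The 17 clusters fell into a few endothelial classes. Most cells were Plvap-high, carrying the transcript of the diaphragm protein of fenestrated capillaries (1224 CPM in WT and 1414 CPM in VEGF/LysM), and formed 6 clusters with 3962 WT and 2001 VEGF/LysM cells. Among these, cluster 6 had Esm1, Npr3 and Cyp26b1 among its leading genes, clusters 3 and 9 had venous markers such as Bgn, Sele and Vcam1, and cluster 4 was led by immediate-early genes. Capillary-like cells, of the continuous type, were low in Plvap and led by Cd36, Car4, Rbp7 and Cxcl12, with 836 WT and 727 VEGF/LysM cells. Arterial-like cells (249 and 248) were led by Npnt, Tspan8 and Lgr5. They were named from the enrichment of the arterial list as a whole, since none of that list was among their 10 leading genes. Tip-like cells (441 and 328) were led by Apln and included Kcne3. Cluster 8 mixed lymphatic and venous markers, Lyve1, Mmrn1, Ccl21a and Vwf, and was left unnamed. Cluster 10 (70 and 60 cells) was led by erythroid genes such as Hba-a1 and Hbb-bs, with the capillary marker Car4, and was kept among endothelial cells without a class name. Cluster 13 (5 and 7 cells) was led by the proliferating markers Top2a, Mki67 and Cenpf and was kept in the same way.

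The non-endothelial cells that passed the gate were few. Myeloid-like cells made up 1.53% of retained WT and 2.39% of VEGF/LysM cells, adrenocortical-like cells 0.62% and 1.20%, lymphoid-like cells 0.19% and 0.52%, and mural-like cells 0.07% and 0.08%. The myeloid-like cells included 8 WT and 4 VEGF/LysM cells with B-cell transcripts. The sort sets these shares. All endothelial clusters together made up 97.6% and 95.8% of retained cells, a difference that took the other direction under the stricter cell filter (1.41 points).

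Capillary-like and arterial-like cells made up more of the endothelial cells in the VEGF/LysM library, and Plvap-high cells made up less. These shares came from the clustering that left out genes differing between the libraries. Capillary-like cells were 916 of 5675 WT cells (16.1%, 15.2 to 17.1) and 866 of 3534 VEGF/LysM cells (24.5%, 23.1 to 26.0), a difference of 8.36 points (6.64 to 10.1). Arterial-like cells were 4.23% (3.72 to 4.79) and 6.48% (5.69 to 7.34). Plvap-high cells with tip-like cells were 78.5% (77.4 to 79.6) and 67.9% (66.3 to 69.4), a difference of -10.7 points (-12.5 to -8.77). Single Plvap-high clusters went both ways. Those with 911 WT and 281 VEGF/LysM cells, 705 and 173, and 1020 and 380 made up less of the VEGF/LysM library. Those with 636 and 659 cells, and 959 and 746, made up more. The tip-like cluster in this clustering held more proliferating markers (Top2a, Mki67 and Cenpf) than tip-cell markers (Apln and Kcne3) among its leading genes, so no share is given for it alone. Cells with lymphatic and venous markers were 0.72% and 0.99%. In the clustering used for gene ratios they were 1.69% (1.37 to 2.06) and 3.35% (2.78 to 4.00), so this share depended on the clustering. In this clustering 8 WT and 4 VEGF/LysM cells led by B-cell genes such as Igkc and Cd79a counted among the endothelial cells, and without them the capillary-like difference was 8.37 points. The share of capillary-like cells depended on where cluster borders fell: over the 7 rounds of that clustering it ran from 3.61% to 16.6% in WT and from 11.2% to 24.8% in VEGF/LysM, while the difference stayed between 7.62 and 8.36 points. The VEGF/LysM cells were deeper, and both the sort and the dissociation can select among vessel types. Under alternatives the arterial-like difference reached 4.09 points (looser filter) and the Plvap-high difference ran from -14.7 (clustering on thinned cells) to -4.33 points (stricter filter).

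**Figure D1:**
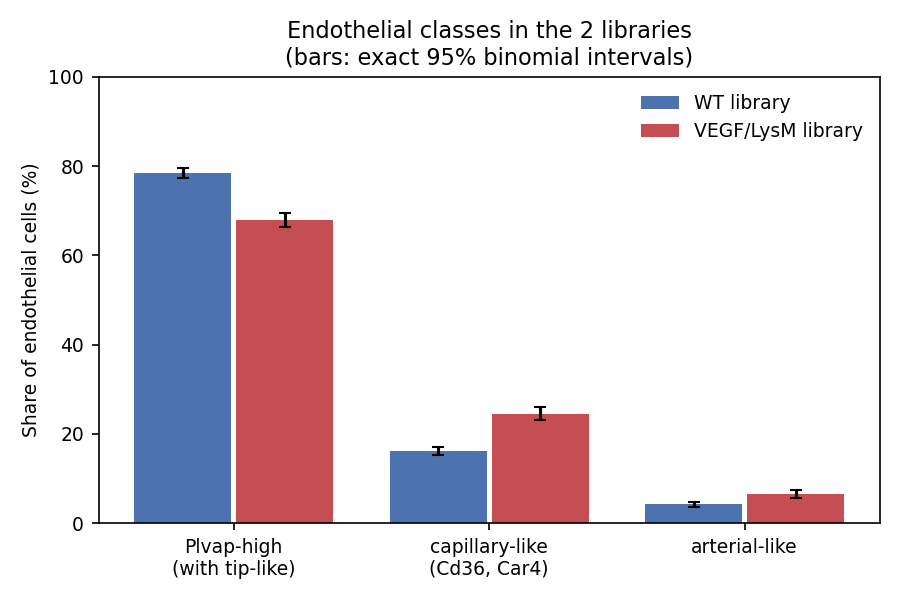
Share of endothelial cells (%) in the WT and VEGF/LysM libraries for Plvap-high with tip-like, capillary-like and arterial-like cells; bars on the columns are exact 95% binomial intervals. Capillary-like cells stood at 16.1% and 24.5%, and Plvap-high with tip-like cells at 78.5% and 67.9%.

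In all endothelial cells, the gene whose interval lay farthest below equal levels in the VEGF/LysM library, among genes with at least 20 CPM, was Cyp26b1, which encodes an enzyme that breaks down retinoic acid. It stood at 383 CPM in WT and 108 CPM in VEGF/LysM, 3.55-fold lower (log2 -1.83, -1.94 to -1.72), and lower in 11 of the 11 clusters with at least 20 UMIs. Sema3c, a secreted guidance cue, was at 35.7 and 11.3 CPM (log2 -1.66, 7 of 7 clusters), and the integrin gene Itga8 at 24.99 and 7.99 CPM (log2 -1.64). Bmp2, a ligand of the BMP family, was at 101 and 51.8 CPM (log2 -0.97, 8 of 8 clusters). Several large genes were lower as well: Pcdh9 (229.7 and 100.8 CPM, log2 -1.19), Nkain2 (-1.30), Nlgn1 (-1.21), B3galt1 (-1.22, in 5 of 7 clusters) and Lrp1b (-1.15). Oit3 (-1.22), Fah (-1.23) and Ifi208 (-1.20) completed the 12. The median gene-body length of these 12 was 175640 bases against 23285 for all measured genes. Over all genes length and log2 ratio were only weakly related (Spearman correlation -0.09), with a median log2 ratio of -0.05 in the longest 10%, and Cmss1 (304865 bases) and Zbtb16 (181926 bases) were among the higher genes.

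Genes of fatty-acid handling were among those higher in the VEGF/LysM library. Fabp4, a fatty-acid binding protein of capillaries, stood at 3823 and 7515 CPM, 1.97-fold higher (log2 0.98, 0.95 to 1.00), and Fabp5 at 177 and 436 CPM (log2 1.30, 10 of 11 clusters). Mgp, a matrix protein of arteries, was at 10.7 and 34.3 CPM (log2 1.69, 1.32 to 2.06), and the retinol-binding gene Rbp7 at 89.8 and 195.5 CPM (log2 1.12). Tspo, a mitochondrial membrane protein, was at 137 and 263 CPM (log2 0.95, 11 of 11 clusters), and the transcription factor gene Zbtb16 at 55.8 and 112 CPM (log2 1.00, 10 of 10 clusters). Hist1h2bc (1.21), Sgpp2 (1.53), Ptn (1.06) and Prss23 (9.18 and 21.8 CPM) were also higher. Cmss1 (log2 1.68) and Mir6236 (113 and 319 CPM) had the highest lower bounds among the genes that the naming rule admits, which leaves out genes over 5-fold higher in non-endothelial cells such as Cd74 (2.26) and H2-Eb1 (1.91), but both overlap repeats of ribosomal RNA genes, so their counts are uncertain. Part of these ratios followed the mix of classes: with an equal mix of classes the log2 ratios were 1.07 for Mgp, 0.71 for Rbp7, 0.49 for Ptn and 0.67 for Fabp4, against -1.79 for Cyp26b1.

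**Figure D2:**
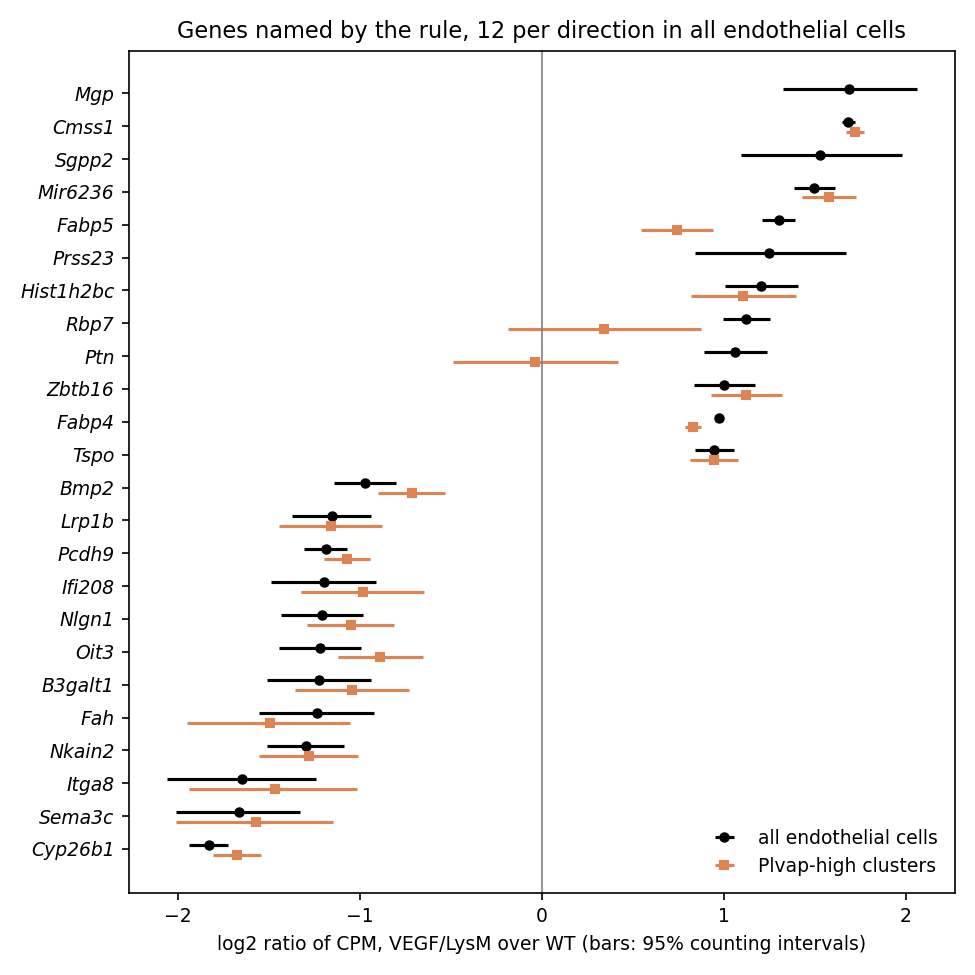
Log2 ratio of CPM, VEGF/LysM over WT, for the 12 genes per direction named in all endothelial cells by the bound of their interval, shown in all endothelial cells (circles) and in Plvap-high cells (squares), with 95% counting intervals. Genes over 5-fold higher in non-endothelial cells, such as Cd74 (2.26), are left out by the naming rule. Cyp26b1 lay at -1.83 and -1.67, while Ptn was at 1.06 in all endothelial cells and -0.04 in Plvap-high cells.

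Within Plvap-high cells alone, the lower genes were much the same. The libraries filled the clusters of this class unequally: cluster 1 held 775 of 3962 WT and 258 of 2001 VEGF/LysM cells, and cluster 9 held 293 and 262. Over alternatives, which include an equal mix of clusters, the Cyp26b1 ratio in these cells ran from -1.87 to -1.36. Cyp26b1 was at 386 and 121 CPM, 3.19-fold lower (log2 -1.67, -1.81 to -1.54), with Sema3c at -1.57, Fah at -1.49, Itga8 at -1.47, Nkain2 at -1.28, Lrp1b at -1.16, Rasa3 at -1.11, Pcdh9 at -1.07, Nlgn1 at -1.05, B3galt1 at -1.04, Ifi208 at -0.98 and Oit3 at -0.89. Higher in VEGF/LysM Plvap-high cells were Zbtb16 (62.3 and 136 CPM, log2 1.12), Tspo (140.2 and 269.8 CPM, log2 0.94) and Fabp4 (1368 and 2435 CPM, log2 0.83). The chaperone genes Hspa1a (1.20) and Hspa8 (0.82), Hist1h2bc (1.11), Lrfn2 (1.29), Ndufs8 (0.93), Ctla2a (0.75) and Ppia (0.72) were higher too, beside Cmss1 (1.72) and Mir6236 (1.58). Rbp7 (log2 0.34, -0.18 to 0.87) and Ptn (-0.04, -0.49 to 0.42) showed no detectable difference in these cells at this depth.

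By cluster, Cyp26b1 was most abundant in cluster 6 (1066 CPM in WT and 315 CPM in VEGF/LysM) and in tip-like cells (879 and 227 CPM), and low in cluster 9 (47.6 and 8.67 CPM). Cyp26b1 was among the leading genes of cluster 6, so its level there also reflects how the cluster was drawn. Fabp4 was highest in capillary-like cells (16939 and 25819 CPM), and it was not higher in arterial-like cells (642 and 612 CPM). Cd74 stood at 11.7 and 90.9 CPM in cluster 6 and at 6.53 and 9.23 CPM in cluster 2.

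**Figure D3:**
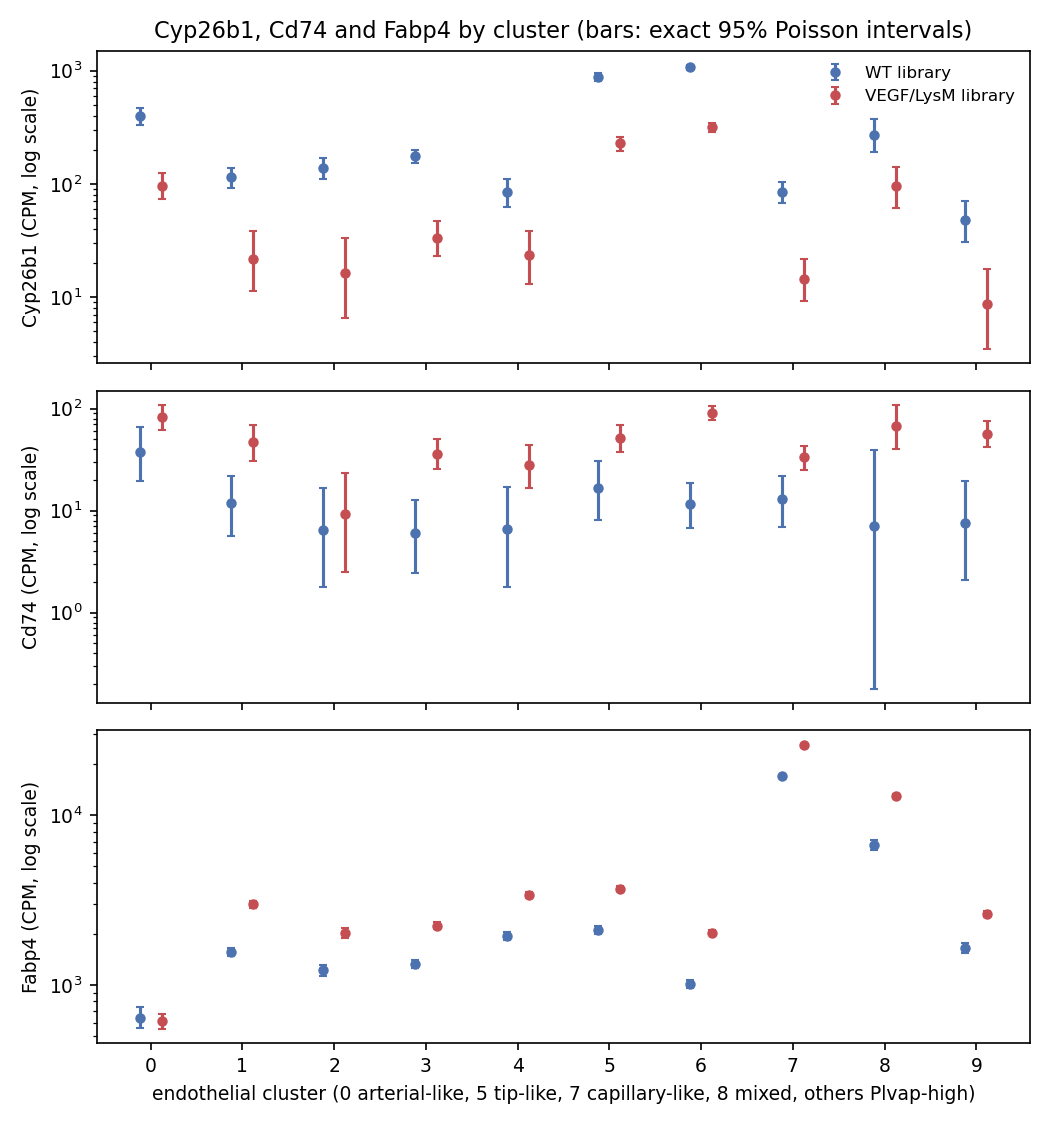
CPM (log axis) of Cyp26b1, Cd74 and Fabp4 in endothelial clusters 0 to 9 of the WT and VEGF/LysM libraries, with exact 95% Poisson intervals. In cluster 6, Cyp26b1 stood at 1066 and 315 CPM and Cd74 at 11.7 and 90.9 CPM.

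The list of genes that VEGF-A induces in endothelial cells had a median log2 ratio slightly below 0 in all endothelial cells. Over 17 measured VEGF-A-responsive genes it was -0.13 (-0.19 to -0.04, percentile 2.62 among matched lists), with 0 members past the fold threshold for list members upward and 5 downward. Among members with at least 20 CPM, the limit for naming members of every list here, Apln (-0.44), Nrarp (-0.43), Adamts1 (-0.37) and Nr4a1 (-0.32) lay lowest. Of these, Nr4a1 is also on the immediate-early and dissociation list, which was lower as well (median -0.29). Adamts1 was among the leading genes of cluster 4, beside immediate-early genes. How much a dissociation response adds to the VEGF-A-responsive median was not tested. In Plvap-high cells the median was -0.10 with a range that included 0 (-0.14 to 0.03, percentile 9.04), and the summed CPM of the list was higher in the VEGF/LysM library (11108 and 11686). It was -0.24 (percentile 0.51) over 15 genes in capillary-like cells, with 5 downward and 0 upward. Of these 5, Igfbp3, Plvap and Esm1, singled out after their values were seen, are markers of other classes (Igfbp3 stood at 2022 and 2039 CPM in Plvap-high cells), and how much RNA of those classes in WT capillary-like cells adds to this median was not tested. It was -0.48 (percentile 0.00) over 7 genes in arterial-like cells, with 4 downward and 0 upward (-0.33 without the Stab2-type cells). Capillary markers, which share Esm1, Plvap, Kdr and Flt1 with this list, were lower there too. Their median was -0.60 (-0.33 without the Stab2-type cells). How much capillary RNA in WT arterial-like cells adds to the VEGF-A-responsive median was not tested. In tip-like cells the VEGF-A-responsive median was -0.11 (-0.22 to 0.04, percentile 7.14), with a summed CPM of 13960 and 14242, and 0.07 with cells thinned to 1000 UMIs. VEGF ligands and receptors had a median of -0.02 (percentile 50.4), with Flt4 and the co-receptor Nrp2 (-0.34) lower and Vegfc higher (0.31, but -0.07 with an equal mix of classes).

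Markers of arteries were higher in the VEGF/LysM library over all endothelial cells. The median of 14 arterial markers was 0.46 (percentile 100), and Mgp, Fbln5 (0.75), Fbln2 (0.67) and Eln (0.46) were the highest of those with at least 20 CPM. It was 0.12 with an equal mix of classes, and -0.14 (percentile 17.4) over the 7 markers measured in Plvap-high cells. In arterial-like cells, which were named from this list and include the Stab2-type cells, it was 0.30 (0.15 to 0.50, percentile 99.75). There 6 of 13 markers were past the fold threshold upward and 1 downward. Capillary markers had a median of 0.04 (percentile 88.7): Cd36 (1265 and 2094 CPM, 0.73), Car4 (0.58) and Gpihbp1 (0.56) were higher and Exoc3l2 (-0.28) lower. Cd36 was higher in only 4 of 12 clusters, Car4 in 3 of 4 and Gpihbp1 in 10 of 13. Venous markers had a median of -0.08 (percentile 28.5), with Tmem252 (1.05) higher and Bgn (-0.62), Vcam1 (-0.41) and Ephb4 (-0.22) lower. Tip-cell markers had a median of -0.11 (percentile 13.5), with Apln and Trp53i11 (-0.15) lower and Lamb1 (0.40) and Esm1 (0.21) higher. In Plvap-high cells their median was -0.28 (percentile 0.50), with a range that included 0 (-0.39 to 0.02). There 4 members were past the fold threshold downward and 2 upward, and the summed CPM was higher in the VEGF/LysM library (1341 and 1516).

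The caveolar genes Cavin3 (0.36), Cav1 (0.29) and Ehd2 (0.26) were higher in the VEGF/LysM library and Ehd4 (-0.20) was lower. The fenestrae and caveolae list had a median of 0.17 (percentile 99.6) in all endothelial cells, -0.06 with an equal mix of classes, and 0.04 (percentile 87.0, mean -0.02) in Plvap-high cells. Cav1 (-0.06) and Ehd2 (-0.06) also changed direction with an equal mix. Notch signalling had a median of -0.06 (percentile 28.6), with Nrarp and Notch4 (-0.16) lower and Jag2 (0.30) and Jag1 (0.36, but -0.01 with an equal mix) higher. Angiopoietin and Tie genes had a median of -0.11 (percentile 15.7) and a mean of 0.03, with lower ratios for Foxo1 (-0.25), Tek (-0.13, but 0.03 with an equal mix of clusters), Tie1 (-0.12, but 0.01 under the stricter filter) and Ptprb (-0.11). Junction genes had a median of 0.04 (percentile 88.4), with Cldn5 (0.23) higher, Jam3 at -0.12 (-0.24 to 0.00), and Gja4 (0.29) and Jam2 (0.16) turning to -0.11 and -0.01 with an equal mix of classes.

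Most measured genes of leukocyte adhesion and inflammation were lower in the VEGF/LysM library, and genes of antigen presentation were higher or differed little. The adhesion list had a median of -0.43 (percentile 0.01), with 7 of 10 measured members lower past the same threshold and 1 higher. Its summed CPM was level (704 and 700). The lower members included Icam1 (77.5 and 56.4 CPM, -0.46), Vcam1 (-0.41) and the inhibitor of inflammatory signalling Tnfaip3 (-0.39), while the chemokine gene Cxcl9 was higher (54.0 and 103 CPM, 0.93). In Plvap-high cells the median was -0.46 (percentile 0.00), and it ran from -1.06 to -0.20 over alternatives. In capillary-like, tip-like and arterial-like cells only 5, 4 and 3 members were measured, and the ranges of the median included 0. The antigen presentation list had a median of 0.36 (percentile 99.99), with 7 of 13 members past the threshold upward and 0 downward. Cd74, the invariant chain of MHC class II, stood at 11.2 and 53.8 CPM (log2 2.26, 1.92 to 2.62) and was higher in 8 of 8 clusters, with log2 ratios from 1.45 to 2.42 over alternatives. H2-Eb1 (6.62 and 24.9 CPM, 1.91), H2-Ab1 (16.5 and 38.9 CPM, 1.24) and the immunoproteasome gene Psmb8 (129 and 219 CPM, 0.76) were higher as well.

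In Plvap-high cells, Cd74 stood at 8.87 and 55.9 CPM (log2 2.66, 2.20 to 3.14) and the antigen presentation median was 0.35 (percentile 100). The interferon response list had a median of 0.02 (percentile 84.3) in all endothelial cells and 0.08 (percentile 98.1) in Plvap-high cells, the latter -0.00 with an equal mix of clusters. Among its members Bst2 (0.63), Ly6a (0.45) and Isg15 (0.36) were higher and Ifi44 (-0.33) lower.

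Lists of matrix, signalling, angiocrine and vasoactive genes had medians close to 0 in all endothelial cells. Basement membrane and matrix genes had a median of 0.01 (percentile 75.7): Lamb2 (0.42) and Lamb1 (0.40) were higher, Col15a1 (-0.31) was lower, and Col18a1 (0.52) turned to -0.15 with an equal mix of classes. TGF-beta and BMP signalling had a median of -0.02 (percentile 55.7) and a mean of 0.05, and the target genes Id1 (0.42), Id3 (0.38) and Smad6 (0.28) were higher. Tgfb2 (0.41) turned to -0.05 with an equal mix of clusters. Angiocrine ligands had a median of 0.04 (percentile 87.7), with Bmp2 and Hbegf (-0.43) lower, Bmp6 (0.44) higher, and Cxcl12 (0.43) at -0.02 with an equal mix of classes. In Plvap-high cells the angiocrine median was -0.15 (percentile 2.84), and 0.08 under the stricter cell filter. Vasoactive mediators had a median of -0.00 (percentile 66.8) and a mean of 0.04, with Ramp2 (0.37) higher and Ptgs1 (-0.29), Npr1 (-0.24) and Ednrb (-0.12) lower.

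Lists of lipid uptake and energy metabolism had medians above 0, although most respiratory chain and glycolysis genes differed little. The lipid list had a median of 0.62 (percentile 100), with 10 of 15 members past the fold threshold upward. Fabp5, Fabp4, Cd36 and Pparg (0.82, in 4 of 8 clusters) were higher. It was 0.26 with an equal mix of classes and -0.03 (percentile 49.7) in Plvap-high cells, where 4 members were past the threshold upward and 5 downward. In capillary-like cells, named from Cd36 and Car4, it was 0.30 (0.22 to 0.40, percentile 100), with 5 of 13 members upward and 0 downward. In tip-like cells it was 0.19 (0.02 to 0.45) and in arterial-like cells -0.25 (-0.50 to 0.05), over 8 members in each. The oxidative phosphorylation list had a median of 0.27 (percentile 100) in all endothelial cells and 0.27 (percentile 100) in Plvap-high cells, with 4 and 6 of 16 members past the threshold upward and 0 downward. Its leading members Cox5a (80.5 and 123 CPM, 0.62), Ndufb8 (0.55), Ndufa4 (0.43) and Cox5b (0.33) were each higher in 11 of 11 clusters. Glycolysis had a median of 0.16 (percentile 99.7), with 5 of 13 members past the threshold upward, among them Pfkp (0.57), Gapdh (0.42), Eno1 (0.41) and Tpi1 (0.35). Hypoxia response genes had a median of 0.07 (percentile 92.2), with Ldha at 0.16 and Ddit4 at -0.29. P4ha1 (0.10) and Pfkfb3 (-0.10) had intervals that included 0.

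The immediate-early and dissociation list had a median of -0.29 (percentile 0.00), with 7 of 18 members past the threshold downward and 3 upward. In Plvap-high cells its median was -0.14 (percentile 0.86), with 2 downward and 2 upward. Egr1 (351 and 205 CPM, -0.77) and Fos (-0.57) were lower, while Hspa1a (0.95) and Hsp90aa1 (0.51) were higher. Shear stress response genes had a median of 0.06 (percentile 91.9), with Klf2 (0.26) higher, Slco2a1 (-0.35) lower, Cdkn1b at 0.15 (-0.03 to 0.32), and Aqp1 (0.54) at -0.01 with an equal mix of classes. Endothelial transcription factors had a median of -0.08 (percentile 13.4), with Sox17 (0.45) higher and Maf (-0.38), Ets2 (-0.20) and Erg (-0.17) lower. The p53 and apoptosis list had a median of 0.01 (percentile 72.6), in which Cdkn1a (0.52, in 12 of 12 clusters) and Ccng1 (0.40) were higher and Trp53inp1 (-0.30) and Mdm2 (-0.24) lower. The cell cycle list had a median of 0.74 (percentile 100) over 7 measured genes, of which Hmgb2 (0.36) alone reached 20 CPM. The 5 WT and 7 VEGF/LysM cells of cluster 13 held 22.6% and 30.6% of the UMIs of this list, and without them 3 genes remained measured, with a median of 0.29. It was 0.02 under the stricter cell filter.

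**Figure D4:**
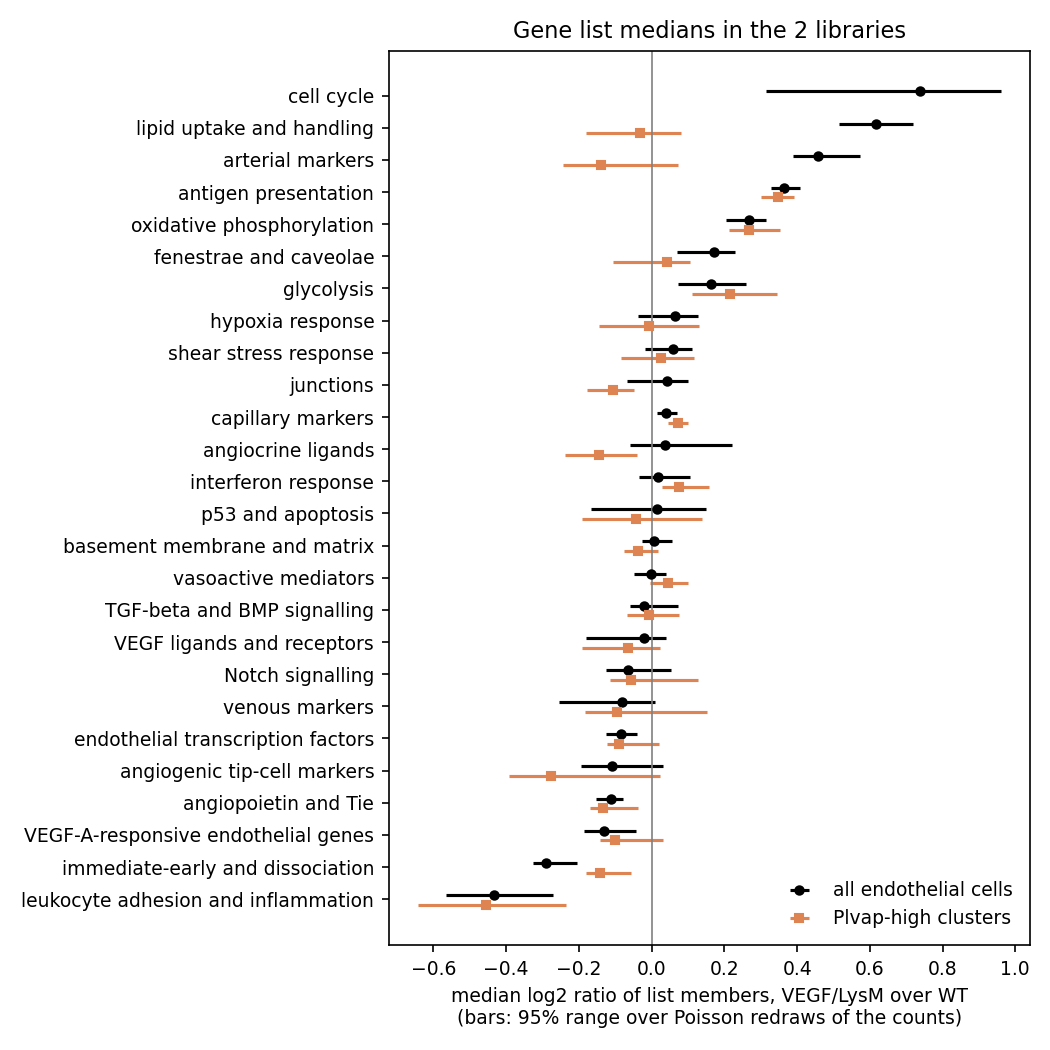
Median log2 ratio, VEGF/LysM over WT, of 26 gene lists in all endothelial cells (circles) and of 25 in Plvap-high cells (squares), with bars for the 95% range over 1000 Poisson redraws. Antigen presentation (0.36 and 0.35) and oxidative phosphorylation (0.27 and 0.27) were alike in both, while lipid uptake was at 0.62 and -0.03.

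In capillary-like cells, Fabp5 (709 and 1641 CPM, log2 1.21), the zinc transporter gene Slc39a8 (1.08), Ubd (1.40) and Trappc5 (1.48) were higher in the VEGF/LysM library, beside Cmss1 (1.38) and Mir6236 (1.15). Igfbp5 (368 and 46.6 CPM, -2.98), Meis2 (456 and 99.8 CPM, -2.19), Maf (-3.07), Rarb (-3.09), Fos (-2.46) and Cyp26b1 (-2.54) were lower. The WT cells of this class also held more Plvap (170 and 92.6 CPM), the transcript that marks the main class. Igfbp5 (3454 and 3345 CPM) and Meis2 (4546 and 4415 CPM) were abundant in Plvap-high cells, and how much RNA of that class adds to the lower genes was not tested.

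In tip-like cells, Zbtb16 (1.82), Hspa8 (1.20), Ctla2a (0.92) and Fabp4 (0.82) were higher, beside Cmss1 (1.60) and Mir6236 (1.15). Cyp26b1 (879 and 227 CPM, -1.95), Nkain2 (-1.87), Kazn (-1.66), Lrp1b (-1.58), Bcl6b (-0.93) and Tinagl1 (-0.86) were lower. The Cyp26b1 ratio ran from -2.15 to -0.62 over alternatives.

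In arterial-like cells, Mgp (117 and 373 CPM, 1.67), Tspo (250.0 and 536 CPM, 1.10), Stmn2 (1.55) and Memo1 (1.95, from 6 and 46 UMIs) were higher in the VEGF/LysM library, beside Cmss1 (1.59) and Mir6236 (1.30). Stab2, a scavenger receptor of sinusoids, had the largest difference (log2 -7.84, -13.2 to -5.34), with 116 and 1 UMIs. A group of 14 WT cells carried it, with 30699 of the 316052 WT UMIs of this class. Ehd3 (-3.03), Maf (-2.58), Bmp2 (-2.39), Tmem64 (-2.13) and Cyp26b1 (-2.04) were lower too. Without the Stab2-type cells these became -1.44 for Ehd3, -0.26 for Maf and -1.60 for Cyp26b1, Bmp2 and Tmem64 had too few UMIs left to be measured, and Maf was at 0.16 with VEGF/LysM cells thinned to the WT depth.

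With every cell thinned to 1000 UMIs, which left out 37.0% of WT and 7.86% of VEGF/LysM endothelial cells, the share of cells with a Cyp26b1 UMI was 16.97% (15.8 to 18.2) in WT and 6.78% (5.94 to 7.70) in VEGF/LysM. Cells with a Cd74 UMI were 0.81% (0.54 to 1.16) and 4.07% (3.41 to 4.80), and cells with a Fabp4 UMI 68.3% and 80.3%. Unthinned, the shares were 19.0% and 10.4% for Cyp26b1, 1.11% and 7.72% for Cd74, and 72.3% and 86.8% for Fabp4. In thinned adrenocortical-like cells, Cyp26b1 was seen in 10.3% of 29 WT and 0% of 36 VEGF/LysM cells, Cd74 in 0% of either and Fabp4 in 48.3% and 44.4%. These cells also held endothelial RNA, with a Kdr UMI in 48.3% and 41.7% of them. Their shares thus do not measure background RNA alone. Unthinned medians in these cells were 1794.5 and 3827.5 UMIs. Genes per thinned endothelial cell were 764 and 751 (856 and 1435 unthinned). Thinned cells with at least 2 UMIs of cell cycle genes were 0.62% in WT and 0.92% in VEGF/LysM.

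The arterial markers set arterial-like cells apart from other endothelial cells about equally in both libraries, by a median log2 of 3.52 in WT and 3.91 in VEGF/LysM, with a gene-wise median difference of 0.07. Tip-cell markers set tip-like cells apart by 1.47 and 1.44 (difference -0.14). Capillary markers were lower in capillary-like cells than in the rest (-0.56 and -0.88, difference -0.28), since Plvap and several other members of that list were highest in Plvap-high cells.

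Transcripts of other cell types in the endothelial cells differed between the libraries mainly for red blood cells. The erythroid list, which marks cluster 10, stood at 454 CPM in WT and 732 CPM in VEGF/LysM (1.61-fold), and haemoglobin genes at 452 and 730 CPM (1.62-fold). Adrenocortical (343 and 356 CPM, 1.04-fold) and myeloid transcripts of the marker list (240.4 and 238 CPM, 0.99-fold) were level, and mitochondrial (1.10-fold) and ribosomal-protein transcripts (1.06-fold) were close. A second myeloid list of 12 genes, most of its UMIs from Fcer1g, was higher (108 and 148 CPM, log2 0.46, 0.33 to 0.59). Mural (0.85-fold) and platelet transcripts (0.80-fold) were lower, and chromaffin (0.69-fold, 0.39 to 1.22) and fibroblast transcripts (0.65-fold, 0.33 to 1.26) showed no detectable difference at this depth. Lymphoid transcripts gave 8 UMIs in each library, glial 34 and mesothelial 1.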

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

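The tests of both explanations weighed here for the capillary-like share were chosen after that share had been seen.

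Capillary-like cells made up 24.5% of VEGF/LysM and 16.1% of WT endothelial cells. A depth gap at the UMI minimum could remove shallow capillary-like cells from the WT library. That minimum left out only 138 WT and 0 VEGF/LysM barcodes. Under the looser cell filter, which had no UMI minimum, the difference was 10.5 points. These values argue against the minimum used here as the cause. A thinning test could not decide the question. VEGF/LysM cells thinned to the WT depth and filtered again still had a capillary-like share of 23.2% (21.8 to 24.7), above the upper bound of 17.1% in WT. But 3263 of 3534 VEGF/LysM endothelial cells still passed, with class labels from full depth. Losing so few cells could not have brought the share down to that bound. Cells lost before the barcodes were called could not be seen, so a loss at that earlier step stays open. More periadrenal fat in the VEGF/LysM dissociation could also raise this class, and it cannot be told apart from a difference in the gland, since summed adipocyte transcripts in capillary-like cells were 0.82-fold those of WT (0.64 to 1.06) and in Plvap-high cells 0.73-fold (0.36 to 1.45), intervals on both sides of 1. If the capillary-like cells of both libraries came from fat, their adipocyte transcripts would be level whatever their share. Over all endothelial cells the ratio was 1.09, but capillary-like cells held 111 of 155 WT and 150 of 203 VEGF/LysM adipocyte UMIs, so that ratio rises with the share itself and decides nothing. Of the 10 adipocyte genes, 9 gave UMIs in WT endothelial cells and all 10 in one library or the other, none above 11.3 CPM over all endothelial cells. Summed, they stood at 110 CPM in WT and 90.8 CPM in VEGF/LysM capillary-like cells, against 4.24 and 3.08 CPM in Plvap-high cells. In both libraries this class thus held more adipocyte RNA than the main class. The CD31+ gate would remove adipocytes but not the vessels of fat. The difference named by the design, VEGF/LysM against WT, also stays open and untested.

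Gpihbp1, which carries lipoprotein lipase across capillary endothelium, differed between classes in its direction. It was higher in the VEGF/LysM library in Plvap-high cells (log2 0.44) and capillary-like cells (0.55) and lower in arterial-like cells (-0.80, 250.0 and 144 CPM), and the difference between classes was not tested. The WT arterial-like cells include 14 cells of another type, with sinusoid transcripts. Without the Stab2-type cells, Gpihbp1 in arterial-like cells was at -0.25 (-0.77 to 0.28), an interval that includes 0, and with CCA integration it was at 0.23, so the opposite direction depends on those cells and on the clustering. Other capillary markers were lower in arterial-like cells too, among them Cd300lg (-1.51) and Cd36 (-0.91), chosen after their values were seen, with 8 of 11 measured members past the fold threshold downward. Without the Stab2-type cells these were -0.70 (-1.40 to 0.00), -0.33 (-0.95 to 0.31) and 6 of 11.

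A group of 14 WT cells, and 1 VEGF/LysM cell, had at least 3 of the sinusoid transcripts Stab2, Dnase1l3, Fcgr2b and Clec4g, a signal that no comparison treats as a class of its own. In the clustering used for ratios all lay within the arterial-like cluster, and so they enter the ratios of that class. In the clustering used for shares, 13 WT and 1 VEGF/LysM cells led by Dnase1l3 and Stab2 formed a small cluster, counted as other endothelial and not as arterial-like.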

How the results depend on the processing

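No paired analysis was possible because each group had 1 library. No scaling moved the median log2 ratio of all measured genes by more than 0.1, and in all endothelial cells it ran from -0.03 to 0.00. Under 21 alternatives, 5 of them chosen after seeing the data, Cyp26b1 in all endothelial cells ran from -1.92 to -1.51, Cd74 from 1.45 to 2.42 and Fabp4 from 0.67 to 1.38. The medians of VEGF-A-responsive genes (-0.16 to -0.06), leukocyte adhesion (-0.66 to -0.31), antigen presentation (0.33 to 0.50) and oxidative phosphorylation (0.21 to 0.33) kept their direction. An equal mix of classes gives no value within a class, and a class with too few cells or a gene with too few UMIs under an alternative gave none there. Of the values of named genes under alternatives, 3918 stayed within their counting interval, 392 moved beyond it in the same direction or had an interval that included 0, and 29 reversed. For list medians these numbers were 1007, 89 and 4.

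Beyond their counting ranges, the leukocyte adhesion median moved to -0.66 under the stricter cell filter and -0.65 with cells thinned to 1000 UMIs. Antigen presentation moved to 0.50 and 0.50 under these and to 0.44 with clustering on thinned cells, and oxidative phosphorylation to 0.33 and 0.32. The capillary-like difference became 10.5 points under the looser filter, 6.07 under the stricter filter, 12.2 with clustering on thinned cells, 5.98 with CCA integration and 5.92 with all variable genes. The arterial-like difference became 4.09 under the looser filter, 3.35 without doublet removal and 3.32 with CCA integration. The Plvap-high or tip-like difference became -4.33 under the stricter filter, -14.7 with clustering on thinned cells, -12.7 with CCA integration, -6.40 without listed and marker genes and -8.26 with VEGF/LysM cells at the WT depth. The share of all endothelial cells among retained cells reversed under the stricter filter, to 1.41 points. The cause was not tested.

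An equal mix of classes, which by its construction removes the difference in class shares, reversed the fenestrae and caveolae median (-0.058), Vegfc (-0.073), Cav1 (-0.058), Ehd2 (-0.062), Jag1 (-0.0075), Gja4 (-0.11), Jam2 (-0.0090), Col18a1 (-0.15), Cxcl12 (-0.022) and Aqp1 (-0.0060). An equal mix of clusters reversed the same median (-0.060), Vegfc (-0.099), Cav1 (-0.060), Ehd2 (-0.073), Jag1 (-0.021), Tek (0.027), Gja4 (-0.17), Col18a1 (-0.15), Tgfb2 (-0.046), Cxcl12 (-0.019), Aqp1 (-0.0038) and the interferon median in Plvap-high cells (-0.0019). The stricter filter reversed Lyz2 (-1.09), Tie1 (0.0063), the angiocrine median in Plvap-high cells (0.080) and Kdr in Plvap-high cells (0.0092). Maf in arterial-like cells reached 0.16 with VEGF/LysM cells at the WT depth, and Gpihbp1 and Cd36 in these cells reached 0.23 and 0.11 with CCA integration. Flt1 in tip-like cells became -0.16 under the looser filter, -0.18 without doublet removal, -0.16 with clustering on thinned cells and -0.031 with CCA integration. The cause of these was not tested.

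Depth limits the smaller classes most: 4092 genes were measured in arterial-like cells and 12277 in all endothelial cells.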

Other observations

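A set of 7 further genes of retinoid handling was looked up after the values of Cyp26b1, Rbp7 and Rarb had been seen, with no list test. Of these, Rarb alone lay past the fold threshold by its interval, as did 3.51% of all measured genes. Rarb, a retinoic acid receptor gene that retinoic acid itself induces, was lower in the VEGF/LysM library in all endothelial cells (421.8 and 249.8 CPM, log2 -0.76, -0.84 to -0.68) and in Plvap-high cells (-0.53). Rara (-0.22), Rarg (-0.22) and the retinal reductase gene Dhrs3 (-0.19) were slightly lower in all endothelial cells, and Rara in Plvap-high cells had an interval that included 0 (-0.38 to 0.09). Rxra (-0.07), Rxrb (-0.08) and Rdh10 (-0.12) had intervals that included 0.

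The myeloid-like cells that passed the CD45- gate, 89 in WT and 88 in VEGF/LysM, were in no comparison of endothelial classes. Csf1r was at 335 and 359.9 CPM in them, and Adgre1 at 128 CPM (88.6 to 179) and 207 CPM (168 to 253). Lyz2 was at 3043 CPM (2837 to 3260) and 2098 CPM (1969 to 2233). These cells also held endothelial RNA, with Plvap at 662 and 603 CPM and Kdr at 1429 and 1274 CPM, and had medians of 2550 and 3456 UMIs against 1163 and 2317 for all retained cells. Doublets and background RNA were not told apart here, so these values describe mixed RNA.

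Of the tests below, those of macrophage RNA and of a chromosome 17 variant were chosen after the result had been seen.

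Cd74 in Plvap-high cells stood at 8.87 CPM in WT and 55.9 CPM in VEGF/LysM, from 37 of 3962 and 178 of 2001 cells. RNA or doublets of macrophages would need 229 CPM of 12 myeloid genes, but 183 CPM (upper bound 195) was present, most of it Fcer1g (169 CPM), which these endothelial cells express, while the other 11 genes, checked after Fcer1g was seen, gave 13.1 CPM of 111 needed. RNA of B cells would need 143 CPM of 8 B cell genes, each under 20 CPM in these cells, and 2.51 CPM was present. This was judged from only 4 VEGF/LysM source cells. The CD45- gate did not remove every cell of either type, since some myeloid-like and B-cell cells were retained. A strain variant linked to Vegfa cannot be told apart from the genotype: H2-Ab1 and H2-Eb1 lie on chromosome 17 too, a variant there could act on Cd74 (chromosome 18) from a distance, and of all genes within 20 Mb 25 of 342 differed (7.31%, 4.79 to 10.6, against 3.51% of all genes). Without MHC and antigen presentation genes, 15 of 320 did (4.69%, 2.65 to 7.61), an interval that includes the 3.39% elsewhere, and the genotype itself and variants elsewhere stay open and untested.

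The respiratory chain list had a median log2 ratio of 0.27 in all endothelial cells. Gene length was argued against as the cause, since the median lay at percentile 99.99 of lists matched on expression and gene-body length. A smaller share of nuclear RNA in the VEGF/LysM library could raise these transcripts and cannot be told apart from a difference in the cells: 8 nuclear-retained transcripts, led by Malat1, had a summed log2 ratio of -0.13 (-0.14 to -0.12), lower but not by the amount set in advance. It passed that amount in Plvap-high cells (-0.15, -0.16 to -0.14) and in tip-like cells (-0.19, -0.22 to -0.16). In capillary-like (0.15) and arterial-like cells (0.06) it went the other way. The respiratory chain medians were 0.27 (0.21 to 0.35) in Plvap-high and 0.30 (0.10 to 0.46) in tip-like cells. They were 0.07 (-0.01 to 0.21) in capillary-like and 0.24 (-0.01 to 0.48) in arterial-like cells, ranges that included 0. The genotype stays open as well.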
